A study of Mus musculus with 4 samples.

How the data were processed

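RNA was profiled on 4 single-colour oligonucleotide arrays, 1 array per sample, from mouse CD4+ YFP+ Ly5.2+ T cells. Per the labels, total RNA was extracted with Qiagen RNeasy, amplified and labelled with the Ambion Message Amp II kit, and carried biotin. The deposited values are GCRMA intensities on a linear scale, made by the authors with GCRMA 1.1.3 per the submitters' processing notes. GCRMA subtracts a background that depends on the sequence of each probe, normalizes the arrays to one another and summarises the probes of a set, so dim probe sets pile up near a floor and their differences are compressed or lost. A group mean below a log2 intensity of 4 is called near the floor, and an exact difference against it depends on the floor. Other settings of that step are not given in the sources used here. The linear scale was read from the values: the lowest intensity per array lay between 1.88 and 1.90, the median between 8.38 and 8.94, and the highest between 57955 and 68331.

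The groups were taken from the sample labels, with 2 arrays for cells whose loxP-flanked Foxp3 gene had been exposed to Cre and 2 for Cre-treated cells with a wild-type Foxp3 gene. No array equalled another. The labels number the samples of each group and do not say whether they came from separate animals or cell preparations. The p-values of single genes therefore measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

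Values were converted to log2 without a pseudocount. Of 45101 probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 had none. Probe sets with several symbols or none were left out, as were 64 control probe sets. Entrez identifiers of 34754 probe sets matched the mouse gene table of assembly GRCm38.p6, which changed 0 symbols. Each of the 18194 genes was represented by the probe set with the highest mean log2 intensity over all 4 arrays. Genes with a mean log2 intensity of at least 4 were tested, which left 8630. The platform annotation used here gives no probe positions, so no coordinates are printed.

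Differences between the groups were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the prior variance on intensity), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The model had 2 residual degrees of freedom and a prior worth 3.31. Gene lists were tested with cameraPR on the moderated statistics with a preset correlation between genes of 0.01, adjusted over the 25 lists with at least 3 tested members. Since cameraPR sets the genes of a list against the other tested genes, its p-values rest on the spread over genes and not between samples. Camera with an estimated correlation and the rotation test fry were run beside it. Camera with an estimated correlation draws on 2 degrees of freedom here, so its p-values can exceed those of cameraPR even where the estimated correlation is no higher. As a description, genes were also counted whose mean difference was at least 1 on the log2 scale and whose groups did not overlap. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

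The gene lists, the tests, the alternatives and the rule for genes named in the text were fixed before the data were examined, with exceptions stated where they occur. The lists were written from general knowledge of T cell biology and not from these samples. The rule named Foxp3, 14 markers and cytokines chosen in advance, up to 4 members of each tested list with the largest difference, and 12 genes per direction. Those 12 were to be the largest changes past the threshold, filled up with the genes of smallest p whose groups did not overlap. Since 0 genes passed, all 12 in each direction came from that second step and are given as values without a call. For some genes that the rule named no difference is given, and these are not in the counts of named genes. S100a4, S100a6, Lgals1, Bach2, Il21r, Runx3, Il12rb1, Ccr2, Ahr, Batf, Ltb4r1, Tbx21, Cd163l1, Gbp2b, Ifitm1, Ifitm2, Ifitm3 and the T cell receptor gamma segments Trgv4 and Trgv1 were chosen after their values were seen.

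The procedure was tested on simulated data for 8630 genes, with 2 arrays per group, 200 changed genes and 20 simulations. At an adjusted p threshold of 0.05 it called 0.3% of genes changed by 1 on the log2 scale, 8.5% of those changed by 2, 48.4% of those changed by 3 and 78.7% of those changed by 4. At a threshold of 0.1 the shares were 1.4%, 26.7%, 73.0% and 90.2%, with a mean of 10.9 unchanged genes called per simulation. A list of 40 genes shifted by 1 was found in 20 of 20 simulations and an unshifted list in 0. Each gene was simulated independently of the others, so this does not test the list p-values under correlation between genes. In the data that correlation was estimated at up to 0.623, for the cell cycle list.

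Alternatives covered the filter, a floor under low values, the variance prior, quantile normalization, centring of the arrays, the mean over probe sets, probe sets tested separately, the replicate number as a block, the leaving out of each array, and a threshold of 0.1. With an array left out, the genes, probe sets and filter were those of all 4 arrays, a choice made after a first version of these values had been seen. That version, in which probe sets and filter were picked again on the 3 arrays left, is given beside it: 77 of 88 named genes then kept their sign under every alternative, not 78, and the effector cytokine list had an adjusted p = 0.000215 in place of 0.69 without wild-type replicate 1. The median log2 intensity over tested genes was 7.37 and 7.21 in deleted and 7.28 and 7.33 in wild-type arrays, which is what centring removed. Same-numbered arrays deviated from their group means with a correlation of -0.298 over genes, so the replicate numbers were not taken as pairs. Some genes of the lists, among them Tigit and Lrrc32, were not analysed here because no probe set carried their symbol alone.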

Results

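The expression data described peripheral mouse regulatory T (Treg) cells after ablation of Foxp3, the transcription factor that defines this suppressive CD4+ lineage. Both groups had received Cre recombinase through the construct HR-MMPCreGFP, and exposure to Cre was read from YFP. In one group Cre could excise a loxP-flanked Foxp3 gene (deleted cells, 2 arrays) and in the other Foxp3 was wild type (2 arrays). All samples were CD4+ YFP+ Ly5.2+ T cells isolated 6 weeks after adoptive transfer. The comparison asked which transcripts of mature Treg cells differ after ablation of Foxp3. Between 35.8% and 36.1% of probe sets per array had a log2 intensity of at least 4.

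Foxp3 itself was lower in both deleted arrays. Its single probe set read 437.8 and 429.8 in deleted cells against 2693 and 2404 in wild-type cells, or 433.8 ± 5.69 against 2549 ± 204.5 (intensity, mean ± SD, n = 2 per group). On the log2 scale Foxp3 was lower by 2.55 (SE 0.28), with 17.0% of the wild-type signal left and an adjusted p = 0.0749 in limma. Where this probe set lies relative to the deleted exons is not given in the sources used here, so the signal left does not measure how much intact Foxp3 transcript remained.

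The Treg signature was lower in deleted cells. Of 38 tested genes of this list, 35 had a lower mean, 27 of them at least 2-fold with no overlap between the groups, and the median difference was -2.03 on the log2 scale. Il2ra, the alpha chain of the interleukin-2 receptor, was lower by 4.33 (SE 0.61) and kept 4.98% of its wild-type signal, with log2 intensities of 5.92 and 4.26 against 9.47 and 9.36, and its other probe set above the filter was lower by 2.48. Ctla4, an inhibitory receptor for CD80 and CD86, was lower by 3.39 (SE 0.29), from a mean log2 intensity of 12.50 ± 0.35 to 9.11 ± 0.12 (SD, n = 2). Itgb8, the integrin subunit that helps to release active TGF-beta, was lower by 5.11 (SE 0.35), which is 34.4-fold. Klrg1, an inhibitory receptor of differentiated lymphocytes, was lower by 5.34 (SE 0.47), and Tnfrsf9, the costimulatory receptor 4-1BB, was lower by 4.37 (SE 0.40). Nrp1 (neuropilin-1) was lower by 2.95 (SE 0.31), though its 4 probe sets above the filter ranged from -2.95 to -0.559. Ikzf2 (Helios) was lower by 1.98 (SE 0.53, and by 1.19 without deleted replicate 1) and Tnfrsf18 (GITR) was lower by 1.72 (SE 0.35). The 3 members with a higher mean were S100a4 (0.64, SE 0.31, adjusted p = 0.632), S100a6 (0.28, adjusted p = 0.831) and Lgals1 (0.07, adjusted p = 0.943). Without deleted replicate 1 S100a4 was at 0.20, and the sign of S100a6 and Lgals1 turned when a deleted array was left out. The list shifted down with an adjusted p = 1.11e-58 in cameraPR, adjusted p = 0.184 with an estimated correlation and adjusted p = 0.0173 in fry. Adjusted over the list alone, 27 genes were past 0.05 and all were lower, against 0 adjusted over all genes tested.

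The 12 genes of smallest p that were lower in deleted cells included Itgb8, Ctla4, Klrg1 and Tnfrsf9. Il10, also on the Treg list, which encodes a suppressive cytokine, was lower by 3.76 (SE 0.30), from a log2 mean of 6.13 to 2.37, close to the floor of the arrays. Gzmb, a cytotoxic granule protease, was lower by 3.59 (SE 0.35), or 12.1-fold. Havcr2, the inhibitory receptor TIM-3, was lower by 3.88 (SE 0.33), the tetraspanin gene Cd81 was lower by 4.52 (SE 0.36) and the activation marker Cd83 was lower by 4.07 (SE 0.36). Neb (lower by 4.15), Lclat1 (9.93-fold) and Laptm4b (26.1-fold) completed this set. Il10, Havcr2 and Neb were near the floor in deleted cells (mean log2 intensity 2.37, 3.0 and 3.06), and with values below 4 raised to 4 they were lower by 2.13, 2.89 and 3.20. Adjusted p was between 0.0668 and 0.0749 for all 12, so that none passed the threshold of 0.05.

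**Figure D1:**
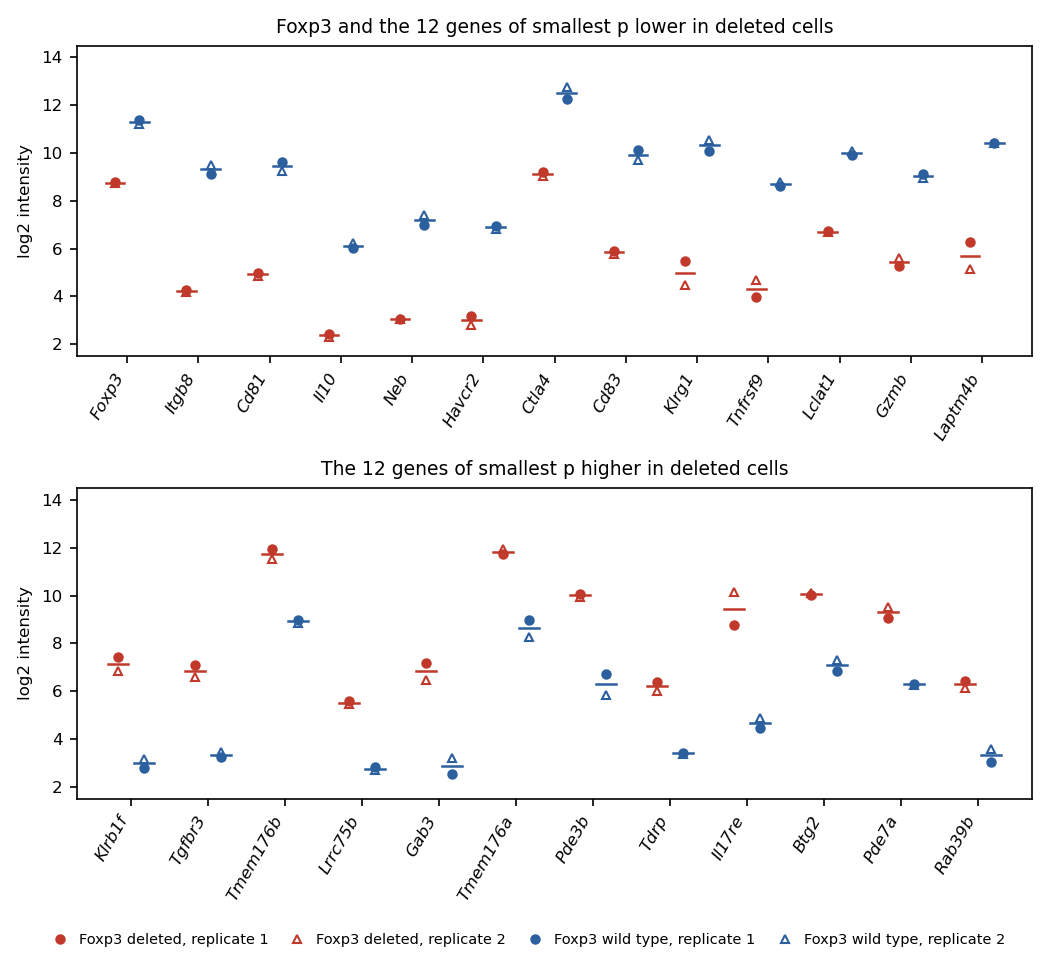
Log2 intensity per array of Foxp3 and the 12 genes of smallest p in each direction, with red for Foxp3-deleted and blue for wild-type cells, circles for replicate 1, triangles for replicate 2 and bars for group means. The groups do not overlap for any gene shown, which the choice of these genes required, and Foxp3 reads 8.77 and 8.75 in deleted against 11.40 and 11.23 in wild-type arrays.

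Genes that Treg cells normally keep low, compared with conventional CD4+ T cells, were higher in deleted cells. Of 18 tested genes of this list 16 had a higher mean, and the median difference was 0.97. Pde3b, a cyclic nucleotide phosphodiesterase known to be repressed by Foxp3, was higher by 3.72 (SE 0.42), from a log2 mean of 6.28 to 10.00. Tgfbr3, the TGF-beta co-receptor betaglycan, was higher by 3.52 (SE 0.35), Themis, a T cell receptor signalling protein, by 3.29 (SE 0.57) and Igfbp4 by 2.40 (SE 0.30), where 5 probe sets above the filter ranged from 0.37 to 3.39. Tgfbr3 was near the floor in wild-type cells (3.34), as was Il2 (3.98), and with values below 4 raised to 4 Tgfbr3 was higher by 2.85. Il2 was higher by 1.53 (SE 0.61, adjusted p = 0.506), and Il7r, the interleukin-7 receptor, by 0.48 (SE 0.35, adjusted p = 0.742). Without deleted replicate 1 the difference was 0.0032 for Il7r and 0.78 for Il2, and the other Il7r probe set above the filter differed by 1.82. The 2 members with a lower mean were Bach2 (-0.24, adjusted p = 0.899, with 3 probe sets from -0.237 to 0.892) and Il21r (-0.21, adjusted p = 0.92), whose signs turned without wild-type replicate 2. The list shifted up with an adjusted p = 7.98e-14 in cameraPR, adjusted p = 0.281 with an estimated correlation and adjusted p = 0.0504 in fry. Adjusted over the list alone, 6 genes were past 0.05 and all were higher, against 0 adjusted over all genes tested.

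The remaining genes higher in deleted cells with the smallest p were of several kinds. Klrb1f, a lectin-like receptor gene of the natural killer complex, was higher by 4.16 (SE 0.38). Btg2, an antiproliferative gene, was higher by 2.98 (SE 0.35) and on its other probe set above the filter by 0.452. Pde7a, a further phosphodiesterase gene, was higher by 3.01 (SE 0.36), with 6 probe sets from 1.32 to 3.01. The adaptor gene Gab3 was higher by 3.96 (SE 0.43), Lrrc75b by 2.74 (SE 0.29) and Tdrp by 2.80 (SE 0.32). Rab39b was higher by 2.97 (SE 0.35), and of its 2 probe sets above the filter 1 had the opposite sign. With probe sets and filter picked again on 3 arrays, the difference for Rab39b was -0.11 without deleted replicate 1 and -0.06 without deleted replicate 2. Klrb1f, Gab3, Lrrc75b, Tdrp and Rab39b were near the floor in wild-type cells (mean log2 intensity 2.97, 2.86, 2.76, 3.40 and 3.31), and with values below 4 raised to 4 the differences were 3.13, 2.82, 1.51, 2.2 and 2.28. With Il17re, Tmem176a and Tmem176b, described with the Th17 list, these genes had adjusted p between 0.0668 and 0.0751.

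Th1 genes were higher in deleted cells. Of 16 tested members 13 had a higher mean, with a median difference of 1.25. Ifng, the signature cytokine of Th1 cells, was higher by 2.48 (SE 0.35), with log2 intensities of 9.90 and 10.00 against 7.70 and 7.23. The chemokine gene Ccl5 was higher by 2.85 (SE 0.38), the chemokine receptor gene Cxcr6 by 2.93 (SE 0.69), the T-box factor gene Eomes by 2.14 (SE 0.76) and Tbx21, which encodes the Th1 factor T-bet, by 1.77 (SE 0.37). Eomes was near the floor in wild-type cells (3.64). Without deleted replicate 1 the difference was 1.92 for Cxcr6 and 1.37 for Eomes. The 3 members with a lower mean were Runx3 (-0.36, adjusted p = 0.784), Il12rb1 (-0.31, adjusted p = 0.871) and Ccr2 (-0.20, adjusted p = 0.946, with 3 probe sets from -0.703 to 0.184), and the sign of Il12rb1 and Ccr2 turned when a deleted array was left out. The list shifted up with an adjusted p = 4.1e-10 in cameraPR, adjusted p = 0.281 with an estimated correlation and adjusted p = 0.0992 in fry. Adjusted over the list alone, 9 genes were past 0.05 and all were higher, against 0 adjusted over all genes tested.

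Th17 genes were likewise higher, 9 of 12 tested members, with a median difference of 1.02. Il17re, a subunit of the receptor for interleukin-17C, was higher by 4.78 (SE 0.55), or 27.4-fold. Its difference was 5.46 without deleted replicate 1 and 4.10 without deleted replicate 2, and further Il17re probe sets, below the filter, were higher by 1.59 and 1.78. Tmem176a and Tmem176b, membrane protein genes expressed in Th17 cells, were higher by 3.21 (SE 0.35) and 2.81 (SE 0.29). Il21, near the floor in wild-type cells (3.84), was higher by 2.16 (SE 0.31) and Il17a by 1.38 (SE 0.52, adjusted p = 0.478), or 0.74 without deleted replicate 1. Ahr, the aryl hydrocarbon receptor, and Batf, an AP-1 factor that Th17 cells need, were lower by 0.82 (SE 0.29, adjusted p = 0.437) and 0.49 (adjusted p = 0.725), and Ltb4r1 was lower by 0.29 (adjusted p = 0.857, and by 0.10 without wild-type replicate 1). The list shifted up with an adjusted p = 1.22e-10 in cameraPR, adjusted p = 0.281 with an estimated correlation and adjusted p = 0.0386 in fry. Adjusted over the list alone, 5 genes were past 0.05 and all were higher, against 0 adjusted over all genes tested.

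The effector cytokine list as a whole did not pass. Ifng and Il21 were higher and Il10 lower, as given above, while Tnf differed by 0.32 (SE 0.44, adjusted p = 0.868), and the sign for Tnf turned without wild-type replicate 2 (-0.19). Il4 lay below the filter, with log2 intensities of 4.69 and 3.87 in deleted against 2.40 and 1.83 in wild-type arrays, and was not tested. Past 0.05 when adjusted over the list alone were 2 higher cytokines and 1 lower one. The 10 tested cytokines had a median difference of 0.57 and an adjusted p = 0.395 in cameraPR, which was 0.0313 without deleted replicate 2 and 0.756, with the opposite sign, without wild-type replicate 2. With probe sets and filter picked again on the 3 arrays left, it was 0.000215 without wild-type replicate 1, where it was 0.69 with those of all 4 arrays.

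**Figure D2:**
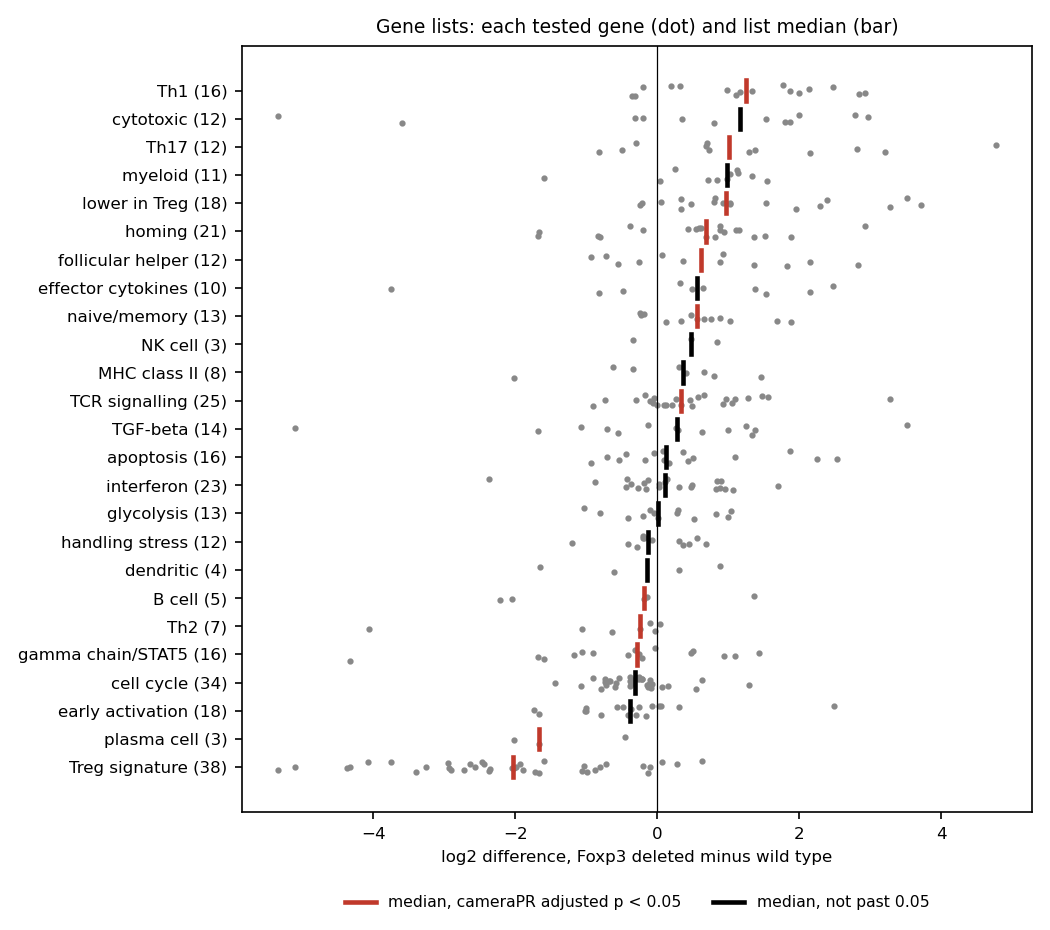
Log2 difference, Foxp3 deleted minus wild type, of each tested gene (grey dots) in the 25 gene lists, with the number of tested genes in brackets and the list median as a bar, red where cameraPR gave an adjusted p below 0.05. The Treg signature lies lowest, with a median of -2.03, and Th1 highest, with a median of 1.25.

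Several lists that describe T cell state shifted by smaller amounts. T cell receptor signalling genes were higher (18 of 25, median 0.33, adjusted p = 0.00271 in cameraPR and adjusted p = 0.281 with an estimated correlation), among them Cd4 by 1.56 (SE 0.52), the kinase genes Fyn by 1.47 (SE 0.29, and 0.576 on its other probe set) and Prkcq by 1.28 (SE 0.35), and Themis. Naive and central memory genes were higher (10 of 13, median 0.56, adjusted p = 0.00708 and with an estimated correlation 0.351), with S1pr1, a receptor for egress from lymphoid tissue, higher by 1.89 (SE 0.33) and its regulator Klf2 by 1.68 (SE 0.41). Of 21 homing genes 15 were higher (median 0.69, adjusted p = 0.00708 and with an estimated correlation 0.281), while Itgae, the integrin CD103, was lower by 1.66 (SE 0.21) and Ccr1 was lower by 1.68 (SE 0.49). Follicular helper genes were higher in 8 of 12 cases (median 0.62, adjusted p = 0.0201 and with an estimated correlation 0.348), with Tox2 higher by 2.83 (SE 0.85), Pou2af1 by 1.83 (SE 0.39) and Cxcr5 by 1.37 (SE 0.49). S1pr1 and Pou2af1 were near the floor in wild-type cells (3.17 and 3.20), and with values below 4 raised to 4 they were higher by 1.06 and 1.03. Without deleted replicate 2 the difference was 1.54 for Tox2 and 0.78 for Cxcr5 and Ccr1 was lower by 1.11, and without wild-type replicate 2 it was 0.95 for Cd4. Each lost its call when a wild-type array was left out. The T cell receptor list had an adjusted p = 0.0579 without wild-type replicate 2, the naive and memory list 0.0997 without wild-type replicate 1, the homing list 0.0536 without wild-type replicate 1 and 0.109 without replicate 2, and the follicular helper list 0.0997 and 0.0669. The follicular helper list also lost its call with the stricter filter (0.546) and with the mean over probe sets (0.222). Genes past 0.05 adjusted over the list alone were 2 higher for T cell receptor signalling, 1 higher for naive and memory, 1 higher and 1 lower for homing, and 2 higher and 1 lower for follicular helper genes, against 0 over all genes tested.

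Lists of cytokine signalling and Th2 genes shifted down. Of 16 genes of the common gamma chain and STAT5 pathway 11 were lower (median -0.28, adjusted p = 0.0201 in cameraPR and adjusted p = 0.348 with an estimated correlation), with Il2ra as given above (Il2ra and Socs2 are also on the Treg list), the kinase gene Pim1 lower by 1.68 (SE 0.27) and Socs2 lower by 1.59 (SE 0.44), but Pim2 higher by 1.44 (SE 0.40). Of 15 measured Th2 genes 7 were tested and 6 of these were lower (median -0.24, adjusted p = 0.00708 in cameraPR and with an estimated correlation 0.334). Il17rb, which encodes a receptor for interleukin-25, was lower by 4.07 (SE 0.48) and Nfil3 was lower by 1.05 (SE 0.38). The other tested members lay between -0.64 (Gfi1) and 0.04 (Stat6). The list was not tested without Il17rb, so its shift may rest largely on that gene. The Th2 cytokine gene Il4, below the filter and so not among the 7, read higher in deleted cells, as given above. Pim2 in wild-type cells (3.72) and Il17rb and Nfil3 in deleted cells (3.86 and 3.90) were near the floor. Without deleted replicate 2 Socs2 was lower by 1.03 and Nfil3 was lower by 0.67. The STAT5 list had an adjusted p = 0.35 without wild-type replicate 1 and 0.241 without replicate 2, and the Th2 list 0.0615 without deleted replicate 1. The STAT5 list also lost its call without a filter (0.182) and with the mean over probe sets (0.544), and the Th2 list without a filter (0.402) and with the stricter one (0.576). With p adjusted over the list alone, 1 STAT5 gene was past 0.05 and higher and 4 were lower, and 1 Th2 gene was lower, against 0 over all genes tested.

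No shift past the threshold was found for early activation (median -0.39, adjusted p = 0.0871), apoptosis (0.13, 0.278), TGF-beta (0.28, 0.815), interferon (0.11, 0.791), glycolysis (0.02, 0.791), cell cycle (-0.31, 0.185) or cytotoxic genes (1.17, 0.749), with the median log2 difference and the adjusted p from cameraPR in brackets. Within them single genes had larger differences, though none passed 0.05 over all genes tested. Of those given here, Tgfbr1, Klrd1 and Gzmk did not pass over their list alone either. Tnfsf8, the CD30 ligand, was higher by 2.50 (SE 0.36), whereas the immediate early gene Nr4a3 was lower by 1.74 (SE 0.41) and Irf4 was lower by 1.66 (SE 0.40). The pro-apoptotic genes Bik and Bcl2l11 were higher by 2.54 (SE 0.47) and 2.26 (SE 0.40), and the 3 probe sets of Bcl2l11 ranged from 0.687 to 2.26. Tgfbr1 was lower by 1.68 (SE 0.51), opposite in sign to Tgfbr3. In the cytotoxic list Klrg1 and Gzmb were lower and Klrd1 and Gzmk were higher by 2.97 (SE 1.22) and 2.79 (SE 0.96). Without deleted replicate 1 these were 1.17 for Klrd1 and 1.30 for Gzmk, which was near the floor in wild-type cells (3.21), and Tgfbr1 was lower by 1.05 without wild-type replicate 2. For the cytotoxic list the median (1.17) and mean (0.39) were above 0 while the test pointed down. The TGF-beta list likewise had a median of 0.28 and a mean of 0.03 with a test that pointed down. Without a filter the interferon list (0.000279) and the apoptosis list (0.0372) passed upwards, and with the stricter filter the early activation list (0.036) and the TGF-beta list (0.0233) passed downwards. Adjusted over the list alone, genes past 0.05 were 2 higher and 1 lower for apoptosis, 1 and 2 for early activation, 1 and 1 for TGF-beta, 1 and 2 for cytotoxic, and 0 for interferon, glycolysis and cell cycle.

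Some of these lists followed single deleted arrays. Cell cycle genes had a median difference of -1.12 for deleted replicate 1 and 0.48 for deleted replicate 2 against the wild-type mean, and an adjusted p = 0.00511, upwards, without deleted replicate 1 and an adjusted p = 1.21e-14, downwards, without deleted replicate 2. Without deleted replicate 2 the cytotoxic and interferon lists had an adjusted p = 0.00101 and an adjusted p = 0.0138, both upwards. The early activation list had an adjusted p = 0.0472 without deleted replicate 1.

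Markers of other cell types that the isolation could have carried over were dim in several lists, but 8 of 9 measured MHC class II genes and 11 of 19 measured myeloid genes were above the filter. Of the B cell list 5 of 14 measured genes were tested and 4 were lower (adjusted p = 0.00384 in cameraPR, adjusted p = 0.351 with an estimated correlation). A probe set of the immunoglobulin mu locus (Ighm) was bright and lower by 2.22 (SE 0.24), at log2 intensities of 10.787 and 11.25 in deleted against 13.278 and 13.195 in wild-type arrays. The shift of the list rested on it and on Cd79b, lower by 2.04 (SE 0.42). Without Ighm, an exclusion chosen after the data were seen, the adjusted p was 0.427, without wild-type replicate 1 it was 0.459 and without wild-type replicate 2 it was 0.0669 and with the mean over probe sets it was 0.0627. The plasma cell list held 3 tested genes, all lower (adjusted p = 0.000277, adjusted p = 0.334 with an estimated correlation). Its leading members, Prdm1 (lower by 2.01, SE 0.32) and Irf4, are transcription factors that Treg cells also use, and Prdm1 also belongs to the Treg signature. Dendritic (median -0.15, adjusted p = 0.791), MHC class II (0.36, 0.791) and natural killer markers (0.47, 0.791, with 1.5 for deleted replicate 1 alone and -0.37 for deleted replicate 2 alone) and handling stress genes (-0.13, 0.791) did not pass in cameraPR. The CD8 T cell markers were all below the filter, and of the erythroid list 2 genes were tested, too few for the list test. When adjusted over the list alone, 2 B cell and 2 plasma cell genes were past 0.05 and lower, 1 MHC class II gene was higher and 1 lower, and 0 were past it in the other lists of this kind.

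Myeloid markers were high in deleted replicate 1. The 11 tested genes had a median difference of 0.99 (adjusted p = 0.113 in cameraPR), which was 1.95 for deleted replicate 1 alone and 0.07 for deleted replicate 2 alone. Without deleted replicate 2 the adjusted p was 4.21e-09, and without deleted replicate 1 it was 0.868 with the opposite sign. It was 0.000808 without a filter and 0.0473 with the replicate number as a block. Lyz2 read 9.69 and 6.30 in deleted against 5.65 and 7.24 in wild-type arrays, and S100a8 read 12.10 and 10.60 against 9.78 and 10.25. The heat shock genes Hspa1a and Hspa1b were highest in the same array, with Hspa1b at 12.69 in deleted replicate 1 and 8.92 in deleted replicate 2 against 10.31 and 9.91. Other heat shock genes of the stress list differed less, with Hspa8 at -0.29, Dnajb1 at -0.20 and Hsp90aa1 at 0.36 between the groups. The handling stress list had an adjusted p = 0.00623, downwards, without deleted replicate 1 and 0.0133, upwards, without deleted replicate 2. The Treg signature, Treg-low, Th1 and Th17 lists kept their direction and call without that array, while the Th2 list did not (0.0615), and deleted replicate 2 alone gave medians of -2.11 for the Treg signature, 0.91 for genes low in Treg cells, 1.1 for Th1 and 1.02 for Th17.

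For Actb and Gapdh the 3' signal exceeded the 5' signal by a large margin on all arrays, and more so on the wild-type arrays. Whether this difference came from RNA quality or from the amplification was not tested. The 3' probe set of Actb exceeded the 5' probe set by 4.91 and 4.47 on the log2 scale in deleted arrays and by 7.26 and 6.60 in wild-type arrays. For Gapdh the differences were 5.89 and 4.17 against 7.24 and 7.08. Signal was therefore more skewed to the 3' end in the wild-type arrays, in which the Th1, Th17 and Treg-low genes were lower and the Treg signature genes were higher. The mean log2 intensity of 9 spiked-in control probe sets was 11.60 and 11.83 in deleted and 12.63 and 12.13 in wild-type arrays.

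**Figure D3:**
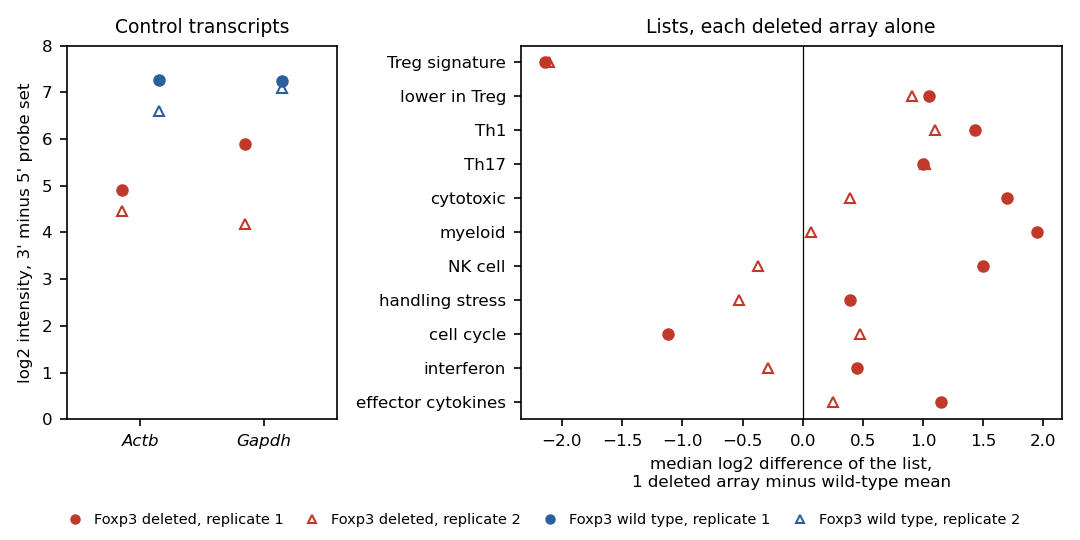
Left, log2 intensity of the 3' minus the 5' probe set of Actb and Gapdh per array, with red for Foxp3-deleted and blue for wild-type cells. Right, median log2 difference of each list for each deleted array alone against the wild-type mean (circles, replicate 1, and triangles, replicate 2), where the Treg signature lies at -2.14 and -2.11 and the myeloid list at 1.95 and 0.07.

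Over the 8630 genes tested, 0 passed an adjusted p of 0.05 in limma. The smallest adjusted p was 0.0668, shared by 10 genes, and 42 genes lay below 0.1, of which 17 were higher and 25 lower in deleted cells. At an unadjusted p below 0.05 there were 858 genes, 449 higher and 409 lower, where 432 are expected by chance. A difference of at least 2-fold without overlap was seen for 906 genes, 481 higher and 425 lower. The groups of 39.7% of all tested genes did not overlap, against 33.3% by chance. Grouping deleted replicate 1 with wild-type replicate 2 instead gave 710 genes 2-fold apart, and grouping arrays of the same number gave 169. The count of 0 depended on processing, since 27 genes passed 0.05 with a stricter filter, 43 after quantile normalization, 60 after centring the arrays and 39 with the mean over probe sets, and Foxp3 passed in each of these.

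The arrays of a group were not in every case the most alike. Over tested genes, deleted replicate 1 correlated with deleted replicate 2 at 0.950 and with wild-type replicate 2 at 0.946, and the wild-type arrays correlated with each other at 0.942. These are correlations across genes, which are not independent replicates. By the median absolute log2 difference over tested genes, deleted replicate 1 was nearer to wild-type replicate 2 (0.335) than to deleted replicate 2 (0.419). Between the wild-type arrays this difference was 0.426. The first principal component held 52.1% of the variance and placed both deleted arrays on one side, at -35.9 and -27.7, and the wild-type arrays on the other, at 51.2 and 12.4. The second held 31.6% and did not follow the groups. It placed deleted replicate 1 (18.0) with wild-type replicate 2 (32.9), and deleted replicate 2 (-36.1) with wild-type replicate 1 (-14.8).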

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

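The crossed pairing and the B cell list without Ighm (0.427) were chosen after the data were seen. Of 88 named genes other than Foxp3, 77 kept the sign of their difference under every alternative that gave them a value. With probe sets fixed, leaving out an array cannot turn the sign of a gene whose groups did not overlap. Most of the 88 were of that kind, and the 12 genes per direction were chosen for it. The count is therefore largely fixed in advance for the arrays left out and is no measure of stability. Genes that the rule named but whose difference is not given are not among the 88. Some of them, such as Bst2 and Klra8, had a higher mean in deleted cells but lay below the wild-type mean in deleted replicate 2. Rab39b turned only with probe sets and filter picked again on the 3 arrays left (-0.1071 to 3.225), and 78 kept their sign where these were fixed. The other 10 turned when 1 array was left out, with ranges of -0.069 to 0.62 for S100a6, -0.12 to 0.25 for Lgals1, -0.59 to 0.12 for Bach2, -0.58 to 0.17 for Il21r, -0.73 to 0.11 for Il12rb1, -0.79 to 0.39 for Ccr2, -1.95 to 3.07 for Hspa1a, -1.19 to 2.57 for Hspa1b, -0.14 to 3.25 for Lyz2 and -0.19 to 0.83 for Tnf, and Bach2 also turned with the mean over probe sets (0.14). With probe sets fixed, the difference of 29 of the 88 moved by over 1.5 times when 1 array was left out. With an array left out, the lone array of its group is assumed to vary like the other group. Foxp3 was lower by 2.47 to 2.63 with any array left out, and its adjusted p then ranged from 0.243 to 0.506, with fewer samples. Foxp3 was past 0.05 with the filter at a mean log2 of 6 (-2.55), after quantile normalization (-2.60), after centring (-2.54) and with the mean over probe sets (-2.55), with an adjusted p between 0.0292 and 0.0394. Over all its alternatives that value ranged from 0.0292 to 0.506.

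The count of genes past 0.05, which was 0, became 27 with the stricter filter (10 higher, 17 lower), 43 after quantile normalization (18 and 25), 60 after centring (26 and 34), 39 with the mean over probe sets (11 and 28) and 42 at a threshold of 0.1. Fewer genes were tested with the stricter filter (6180) and with the mean over probe sets (7670), and the cause was not otherwise tested. It was 0 without a filter, with a floor, without a trend, with a robust prior, with probe sets tested separately and with any array left out. The count of genes 2-fold apart, 906, was 544 with the stricter filter, 528 with the mean over probe sets, and 999 to 1748 with 1 array left out, where 3 arrays overlap less easily.

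With the replicate number as a block 0 genes passed 0.05 and the smallest adjusted p was 0.122. The numbers mark no stated pairing, and same-numbered arrays deviated in opposite directions (-0.298). Under the block the cytotoxic and TGF-beta lists turned upwards (adjusted p 0.809 and 0.796) and the myeloid list passed, and no other list changed its call. A crossed pairing gave 0 genes at 0.05 and 88 at 0.1. It turned the cytotoxic list upwards (0.978), and the early activation (0.0349, down) and myeloid (0.0268, up) lists passed.

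The Treg signature, Treg-low, Th1 and Th17 lists kept their direction and passed under each alternative of filter, floor, prior, normalization, block and array left out and with the mean over probe sets, while lists were not run on separate probe sets. The least extreme adjusted p was 1.89e-29, 8.7e-08, 3.79e-05 and 3.79e-05. With an estimated correlation the values from camera were 0.184, 0.281, 0.281 and 0.281, and 0 of 25 lists passed. The correlations estimated for these lists were 0.00569, 0.036, 0.112 and -0.0667, against the preset 0.01. For the Treg signature and Th17 lists a higher correlation between genes therefore does not account for the lost call. That version of the test draws on 2 degrees of freedom. In fry Treg-low (0.0504) and Th1 (0.0992) did not pass. Of the 12 lists past 0.05, 5 stayed past it with each array left out, the fifth being the plasma cell list. The effector cytokine list turned with the mean over probe sets (0.498) and ranged from 0.0313 to 0.756 with 1 array left out, and from 0.000215 to 0.674, always upwards, with probe sets and filter picked again. Picked again, the naive and memory (0.0861) and follicular helper (0.198) lists also lost their call without deleted replicate 2, the homing list kept its call without wild-type replicate 1 (0.0297), and the cytotoxic list passed downwards without deleted replicate 1 (0.024).

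Lists that did not pass turned direction under some settings, given with their adjusted p, and the cause was not tested. Without a filter these were cytotoxic (0.828), early activation (0.819), stress (0.404) and TGF-beta (0.819). The stricter filter turned interferon (0.906), the mean over probe sets turned MHC class II (0.436) and stress (0.941), and an estimated correlation turned cytotoxic and TGF-beta (0.866). With 1 array left out, in either version, the ranges were 1.08e-14 to 0.479 for cell cycle, 0.0125 to 0.871 for interferon, 2.66e-09 to 0.868 for myeloid, 0.0492 to 0.823 for natural killer, 0.317 to 0.978 for TGF-beta, 0.00101 to 0.871 for cytotoxic, 0.174 to 0.74 for dendritic, 0.0985 to 0.74 for glycolysis, 0.00623 to 0.704 for stress and 0.444 to 0.868 for MHC class II. The deposited values carry no detection calls, and signal near the GCRMA floor limits what dim genes can show.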

Other observations

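The tests of intact cells, of the number of Foxp3 probe sets, of carry-over and of spiked-in controls against the Treg signature were chosen after the results were seen. The last of these replaced 3 earlier tests, the list median (-2.03), the probe sets of 14 of its genes (-1.55) and the mean over spiked-in controls (-1.16).

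Among single genes that respond to interferon, most of them chosen after their values were seen and none past the threshold, Gbp2b and Gbp3, guanylate-binding protein genes, were lower by 4.33 (SE 0.65) and 2.37 (SE 0.53), with adjusted p = 0.115 and adjusted p = 0.253. The mean log2 intensity of Gbp2b in deleted cells was 3.66, near the floor. Ifitm1, Ifitm2 and Ifitm3, a family of interferon-induced membrane proteins, were higher by 4.84 (SE 0.68), 2.31 (SE 0.50) and 1.32 (SE 0.74), with adjusted p = 0.109, 0.237 and 0.68. Ifitm1 read 11.04 and 9.24 in deleted against 5.64 and 4.96 in wild-type arrays. The groups overlapped for Ifitm3. All 3 were higher in deleted replicate 1, the array with high myeloid markers, than in deleted replicate 2, and without it the differences were 3.94 for Ifitm1, 1.82 for Ifitm2 and 0.27 for Ifitm3. The interferon list fixed in advance did not pass (median difference 0.11, adjusted p = 0.791 in cameraPR), and 0 of its genes passed over all genes or over the list alone.

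The next 3 genes were chosen after their values were seen, belong to no tested list, and either missed the threshold or were not tested. A probe set of the T cell receptor gamma segment Trgv4 was higher by 3.07 (SE 0.38, adjusted p = 0.0806), and of the further probe sets of this segment 1 was higher by 3.25 and 1, near the floor, was lower by 0.20. Trgv1 lay below the filter, with log2 intensities of 6.58 and 4.49 in deleted against 2.43 and 2.38 in wild-type arrays. Cd163l1, a scavenger receptor gene known from gamma-delta T cells, was higher by 2.61 (SE 0.36, adjusted p = 0.109) on one probe set and differed by -0.01 on a dim second one, with a wild-type mean log2 intensity of 3.79. Gamma-delta T cells in the preparation may account for these values and for Il17re, Tmem176a and Tmem176b. Over the other gamma-delta markers measured the median difference was 0.0682, below the bound of 0.3 set in advance against that explanation. That bound was wrong, because 4 of 10 markers were measured and 3 of those were below the filter, so it stays open, and of these markers 5830411N06Rik was the brightest (6.93 and 4.98 against 5.57 and 4.97). The isolation on CD4 would remove most such cells. Foxp3 loss in the CD4+ cells themselves stays open as well and was not tested.

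The Foxp3 signal left in deleted cells, 17.0% of wild type, may come from cells that kept an intact gene. Such cells at that share would keep at least as large a share of every Treg transcript, yet 10 of 38 Treg signature genes lay below it on both deleted arrays, 9 of them with a deleted mean log2 intensity of at least 4. For 8 of the 10, such as Ctla4 with 9.52%, every probe set above the filter lay below it, and for Nrp1 and Il2ra not every one did. Of these genes Ctla4 and Nrp1 were the brightest in deleted cells (mean log2 intensity 9.11 and 8.15), and the others lay between 2.37 and 5.84. The values argue against intact cells as the whole source only if array signal is proportional to transcript at such intensities. That was not tested, and a smaller share stays open. Transcript of the deleted allele that still reaches the probe set cannot be told apart from other sources, since there is 1 Foxp3 probe set and its position relative to the deleted exons is not given in the sources used here.

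For the shift of whole lists, the wild-type arrays had the greater loss of 5' signal, which may lower some genes there and, through normalization, raise others. Such a gain would also raise spiked-in controls, yet in every pair of a deleted and a wild-type array the Treg signature median plus the largest spike-in difference was -0.754 or lower on the log2 scale. The controls (means of 11.60 to 12.63) were brighter than that list (wild-type medians of 9.80 and 9.76). The values argue against such a gain as the whole source for that list only if equal amounts were added and the gain was no larger at dimmer intensities. Neither was tested, and a part stays open. Of the 46 Treg-low, Th1 and Th17 genes 15 had at least 2 probe sets, with a median of 0.48 for the smallest difference and every probe set higher in 13, but this covers under 80% of the genes, so direct loss cannot be told apart from a change in expression for them. Myeloid cells in deleted replicate 1 are argued against as the whole source of the 3 lists, since deleted replicate 2 alone, with myeloid markers at 0.07, gave a median of 1 on the log2 scale. A response of the cells to Foxp3 loss stays open and was not tested apart from these.

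The 4 arrays can be parted 2 against 2 in 3 ways, too few for a share under 0.05. The real grouping gave 42 genes at an adjusted p below 0.1 and each of the others gave 0. In the others each group holds a deleted and a wild-type array. A real difference between deleted and wild-type cells would then add to the spread within groups and lower such counts. The other groupings are therefore no measure of what chance alone gives. At an unadjusted p below 0.05 the counts were 858 for the real grouping, 696 with deleted replicate 1 and wild-type replicate 2 together, and 69 with arrays of the same number together. Genes at least 2-fold apart without overlap numbered 906, 710 and 169 in the same order.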
